A study of Arabidopsis thaliana with 6 samples.

How the data were processed

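RNA-seq libraries from 3-week-old Arabidopsis thaliana plants were compared between the Col-0 wild type (replicates 2, 3 and 4) and the fbn6-1 mutant, a T-DNA insertion line in the Col-0 background with the line name GK_159E10 (replicates 1, 2 and 3). Groups and replicate numbers were taken from the sample labels. The labels state Trizol extraction of total RNA, column purification and an Illumina Tru-Seq preparation. They do not say whether the replicates of a genotype were separate plants or pools, so p-values measure the spread between these samples, which may be partly technical.

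The authors deposited raw counts per gene, 1 file per library. Per the submitters' processing notes, the tools were Trimmomatic, FastQC, TopHat2 2.1.1 and featureCounts, with the TAIR10 genome build; their settings, the annotation release, the handling of reads with several matches and the use of strand are not given in the sources used here. Reads from overlapping genes, or from near-identical copies of a gene family, could therefore have been lost or assigned to a neighbour, and values of such genes are uncertain. The files listed 36917 genes, of which 28860 had at least 1 count. Library totals lay between 8668956 and 12287197 counts.

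Gene names, neighbours and overlaps were taken from the RefSeq annotation of TAIR10.1; no coordinates were used in the text, since the release behind the deposited counts is not stated. Plastid and mitochondrial genes are given by their identifiers, because that annotation does not pair these identifiers with names.

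Differences between the genotypes were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test (two-sided) on the counts, TMM normalization, and the filterByExpr filter at its defaults (minimum count 10, minimum total 15), which left 16584 genes. Adjusted p is the Benjamini-Hochberg value over all tested genes, and genes with adjusted p under 0.05 were called. Levels are CPM, counts divided by the TMM-scaled library size, as mean ± SD of 3 libraries per genotype; the errors of log2 fold changes are standard errors (SE). The common biological coefficient of variation was 0.124.

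The following choices were made before the data were examined: the tests, the alternatives, the naming rule and 22 gene lists holding 410 genes. The lists covered the fibrillin family, sulfate uptake and assimilation, sulfur starvation markers, glutathione and phytochelatin synthesis with glutathione transferases, cadmium and heavy metal binding and transport, iron homeostasis, glucosinolate synthesis, the light-harvesting antenna, nuclear photosystem and electron transport subunits, the Calvin-Benson cycle, chlorophyll synthesis, carotenoid, tocopherol and plastoquinone metabolism, the high light and reactive oxygen response, flavonoid and anthocyanin synthesis, jasmonate, salicylic acid defence, the cold, drought and abscisic acid response, heat shock proteins, the circadian clock, leaf senescence, root markers, and flower and flowering markers. All 410 identifiers occurred in the files; 370 carried the listed symbol in the annotation and 40 carried another name or only a locus identifier. The named genes are FBN6, the 10 genes with the largest increase and the 10 with the largest decrease among called genes with a mean of at least 5 CPM and no overlap between the groups, and up to 3 called members per list and direction, by smallest adjusted p. Other genes named in the text were chosen after their values were seen.

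Lists were tested with camera in limma 3.58.1 on voom values, which compares a list with all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 20 lists with more than 1 tested member. Each list was also tested with an estimated correlation and with fry, which asks whether its members move on balance in 1 direction without comparing them with other genes. Members were in addition adjusted over the list alone. Shares of plastid and mitochondrial counts were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Intervals of shares and of the FBN6 ratio are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only.

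The alternatives were RLE factors, library-size scaling without normalization factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of at least 1 CPM in 3 libraries, removal of plastid and mitochondrial genes, an adjusted p under 0.01, a replicate block, and leaving out each of the 6 libraries in turn. On simulated data with the real means and library sizes, in which 200 of 16584 genes were changed, the test recovered 68% of the genes changed by a log2 fold of 1 and 96% of those changed by 2; 12 of the 176 calls were false. In the same simulation the list test called the changed list and 0 of the 20 unchanged lists. Its genes were drawn independently, so it does not show how often that test errs where list members are correlated. The estimated correlation of the real lists reached 0.956, for heat shock proteins.

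No pair of libraries of a genotype matched within sampling noise (chi-square per degree of freedom between 4.53 and 13.9 over the genes compared), so none was treated as another library deposited again. This does not show whether the libraries came from separate plants.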

Results

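The data were gene counts from 6 RNA-seq libraries, 3 of Col-0 wild type and 3 of the fbn6-1 mutant. FBN6 encodes FIBRILLIN6, a member of the fibrillin family of plastid lipid-associated proteins, and the study asked which transcripts differ when this gene is disrupted. The plants were 3 weeks old and grew on potting soil in a 16 h light and 8 h dark cycle at about 120 µmol photons per square metre per second. No cadmium or light stress treatment is named for these libraries. Totals were 10372888, 8820059 and 11426482 counts in wild-type replicates 2, 3 and 4, and 12287197, 9090115 and 8668956 in mutant replicates 1, 2 and 3. Plastid genes took most of them, which left 3257770 to 4955128 counts per library for nuclear genes. The plastid gene ATCG00020 alone held between 25.2% and 31.3% of the counts of a library.

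FBN6 transcripts were nearly absent from the mutant. FBN6 (AT5G19940, chromosome 5) had 1845, 1557 and 2201 counts in the wild-type libraries and 7, 3 and 3 in the mutant libraries. The level fell from 191 ± 3.98 CPM to 0.395 ± 0.113 CPM (SD, n = 3 each), with a log2 fold change of -8.82 (SE 0.17, adjusted p = 4.23e-13, edgeR quasi-likelihood test). Pooled over libraries, the mutant level was 0.215% of wild type (95% interval 0.115 to 0.369), or 464-fold lower (271 to 872). AT5G19950, a tudor domain gene whose annotated end overlaps that of FBN6 by 181 bp on the opposite strand, also fell, from 9.13 ± 0.911 to 2.0 ± 0.313 CPM (log2 fold change -2.20, SE 0.21, adjusted p = 3.57e-05). Its libraries held 82, 85 and 98 counts in wild type and 23, 22 and 17 in the mutant. Because the use of strand in counting is not stated, reads of these neighbours cannot be fully separated. Of the 14 fibrillin genes, FBN1a rose by a log2 fold change of 0.60 (SE 0.11, adjusted p = 0.00649), FBN6 fell, and the other 12 were not called; adjusted over the list alone, 1 was higher and 4 were lower. The FBN1a call was lost without mutant replicate 2 (adjusted p = 0.0536). The list as a whole was called lower by camera (adjusted p = 0.0253; adjusted p = 0.145 with an estimated correlation; adjusted p = 0.0805 without wild-type replicate 2). Without FBN6 the 13 other members were not called (camera adjusted p = 0.247), and the list median of -0.12 became 0.02 under library-size scaling.

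Including FBN6, 633 of 16584 tested genes (3.82%) differed between the genotypes: 245 were higher and 388 were lower in the mutant. At least 2-fold differences were found for 95 higher and 109 lower genes. Among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest decreases after FBN6 were those of FSD1, the iron superoxide dismutase of the chloroplast, MAM3, a methylthioalkylmalate synthase of glucosinolate chain elongation, and AT1G06830, a glutaredoxin. The largest increases among them were those of the chaperone gene HSP70, the cytochrome P450 gene CYP78A8 and 5PTASE11, an inositol polyphosphate 5-phosphatase. In 23.0% of the tested genes the values of the groups did not overlap, where chance gives 10% on average. How far that share varies over other splits of the libraries was not computed. Among the called genes the groups did not overlap in 628 of 633, which follows largely from calling genes on these same values. The balance of the calls depended on scaling: with library size only, the median of all genes moved by 0.13 on the log2 scale and 508 genes were higher against 195 lower (72.3% higher, against 38.7% with TMM). The counts also depended on each library: higher and lower calls numbered 133 and 215 without wild-type replicate 2, 463 and 775 without replicate 3, 127 and 208 without replicate 4, and 109 and 195, 84 and 188, and 120 and 171 without mutant replicates 1, 2 and 3.

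**Figure D1:**
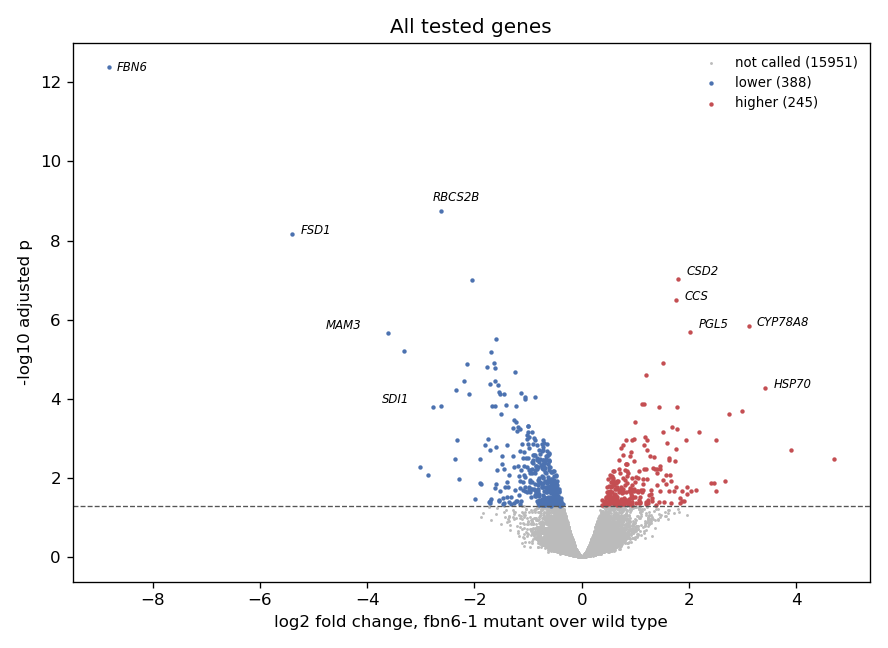
Each point is 1 of the 16584 tested genes, with the log2 fold change of the fbn6-1 mutant over wild type (3 libraries each) on the x axis and -log10 of the adjusted p on the y axis; the dashed line marks an adjusted p of 0.05. The 388 lower and 245 higher genes are coloured, and FBN6 (-8.82) and FSD1 (-5.40) lie farthest to the left.

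Of the superoxide dismutase genes, FSD1 fell while CSD1 and CSD2 rose. FSD1 (AT4G25100, chromosome 4) fell from 398 ± 34.5 to 9.65 ± 4.40 CPM (log2 fold change -5.40, SE 0.23, adjusted p = 6.63e-09), which is 42.1-fold. CSD2 (AT2G28190), the copper/zinc superoxide dismutase of the chloroplast, rose from 76.7 ± 2.22 to 267 ± 10.1 CPM (1.80, SE 0.10, adjusted p = 9.25e-08). CSD1 (AT1G08830), its cytosolic counterpart, rose from 37.8 ± 4.54 to 86.8 ± 3.00 CPM (adjusted p = 2.43e-05). CSD1 overlaps emb2411 on the opposite strand by 211 bp, and emb2411 was also called higher (0.87), so the values of both are uncertain. FSD1, CSD1 and CSD2 were called under all 14 alternatives run. Of the 4 other superoxide dismutase genes, chosen after their values were seen, FSD3 rose (0.77, adjusted p = 0.0463) and FSD2 (0.17), CSD3 (0.35) and MSD1 (-0.13) were not called; with 1 library left out, FSD3 was called only without wild-type replicate 2.

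FSD1, CSD1 and CSD2 belong to the list of the high light and reactive oxygen response, in which 6 of 16 tested members rose and 1, FSD1, fell; adjusted over the list alone, 7 were higher and 2 lower. The other members that rose were the stress-responsive transcription factor genes WRKY33 (0.80, SE 0.14, adjusted p = 0.00618), WRKY40 (1.14), ERF5 (0.92) and ERF6 (1.08). The early light-induced genes ELIP1 (0.27, SE 0.28) and ELIP2 (0.49, SE 0.39) were not called. Their group means lay between 1.29 and 2.37 CPM, so a change could have been missed. The list was called higher by camera (adjusted p = 0.000994, median 0.56; adjusted p = 0.305 with an estimated correlation). WRKY33 was not called without mutant replicate 2 (adjusted p = 0.0503), and it overlaps 2 genes on the opposite strand. Called higher members numbered 3 without wild-type replicate 2 and 2 without mutant replicate 2.

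**Figure D2:**
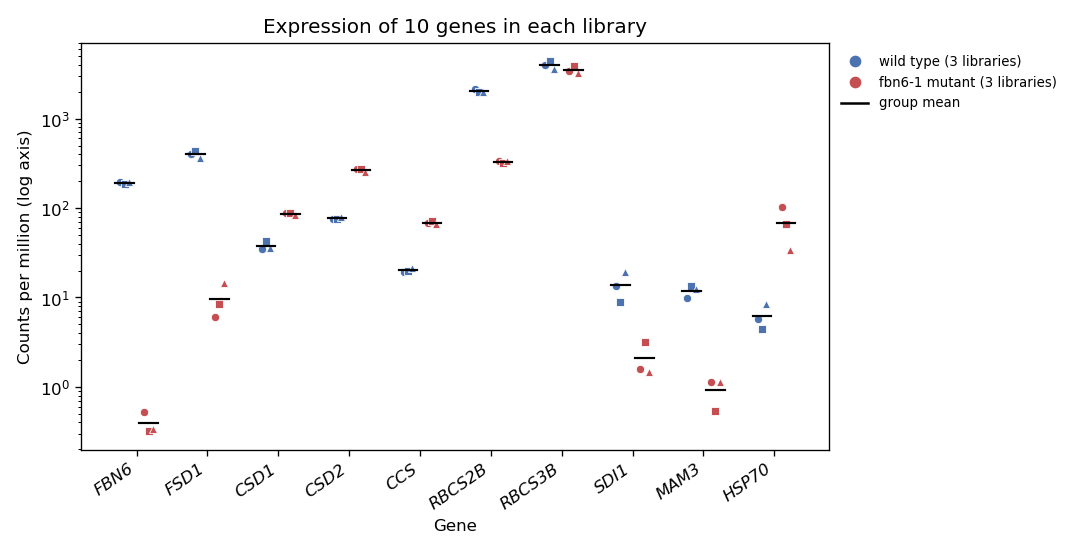
CPM of 10 genes (log axis) in each of the 3 wild-type and 3 mutant libraries; marker shapes separate libraries, bars are group means, and CCS and RBCS3B were added after their values were seen. FBN6, FSD1, RBCS2B, SDI1 and MAM3 are lower in every mutant library than in every wild-type library, CSD1, CSD2, CCS and HSP70 are higher, and the values of RBCS3B overlap.

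Of 8 tested sulfur starvation markers, 7 fell, and adjusted over the list alone 8 were lower; the median log2 fold change was -1.55. Of 23 tested genes for sulfate uptake and assimilation, 11 fell, 0 rose and 12 were not called (15 lower adjusted over the list alone); SERAT2;1 (0.23) and SERAT3;1 (0.19) lay above 0. Both lists, which share the tested members APR3 and SULTR4;2, were called lower by camera (adjusted p = 1.14e-11 and 8.60e-14; adjusted p = 0.142 for both with an estimated correlation). SDI1, named for its induction by sulfur deficiency, fell from 13.8 ± 5.15 to 2.08 ± 0.964 CPM (-2.77, SE 0.31, adjusted p = 0.000156). SHM7, a serine hydroxymethyltransferase gene, fell from 95.3 ± 14.7 to 32.4 ± 6.65 CPM (-1.56, SE 0.15, adjusted p = 4.36e-05), and LSU1 (-1.90) and LSU2 (-2.37) fell as well. The assimilation genes that fell included APR1 and APR3, which encode reductases of adenosine 5'-phosphosulfate: APR1 fell from 82.8 ± 24.0 to 26.9 ± 4.76 CPM (-1.62, SE 0.18, adjusted p = 0.000155), and APR3 fell by 1.39 (SE 0.20, adjusted p = 0.00146). The ATP sulfurylase gene ATPS3 (-1.01, SE 0.13, adjusted p = 0.000673) and the APS kinase gene APK2 (-1.01, SE 0.14, adjusted p = 0.00138) fell to similar degrees. Called members of the starvation list numbered 4 without wild-type replicate 4 and 4 without mutant replicate 2; those of the assimilation list numbered 7 without wild-type replicate 2 or 4 and 6 without mutant replicate 1 or 3.

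Of 22 tested genes for glucosinolate synthesis, a pathway that consumes sulfate-derived sulfur, 15 fell and 1 rose; adjusted over the list alone, 17 were lower and 2 higher. DESeq2 called 12 lower and 0 higher over all tested genes. With library-size scaling 9 were called lower and 1 higher. MAM3 fell from 11.8 ± 1.88 to 0.931 ± 0.346 CPM (-3.62, SE 0.26, adjusted p = 2.14e-06). Other genes of methionine chain elongation fell less: BCAT4 (-1.22, SE 0.15, adjusted p = 0.000379), IPMDH1 (-1.06, SE 0.11, adjusted p = 9.20e-05) and MAM1 (adjusted p = 0.000482). The core-pathway genes CYP79F2 (-1.39) and CYP83A1 (-0.94) and the regulator MYB29 (-0.80) also fell. So did SUR1 (-0.51) and UGT74B1 (-0.61), while the regulator MYB28 (-0.10) was not called. The member that rose was MYB34, a regulator of indolic glucosinolates (0.63, SE 0.16, adjusted p = 0.0461). Of the indolic genes, CYP79B2 (-0.01) and CYP79B3 (-0.60) were not called and CYP83B1 (-0.50, adjusted p = 0.0199) fell. Camera called the list lower (median -0.71, adjusted p = 8.70e-16; adjusted p = 0.142 with an estimated correlation). The MYB34 call was kept, among the fits with 1 library left out, only without wild-type replicate 3, and the lower calls numbered 9, 10, 9 and 8 without wild-type replicates 2 and 4 and mutant replicates 1 and 3.

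**Figure D3:**
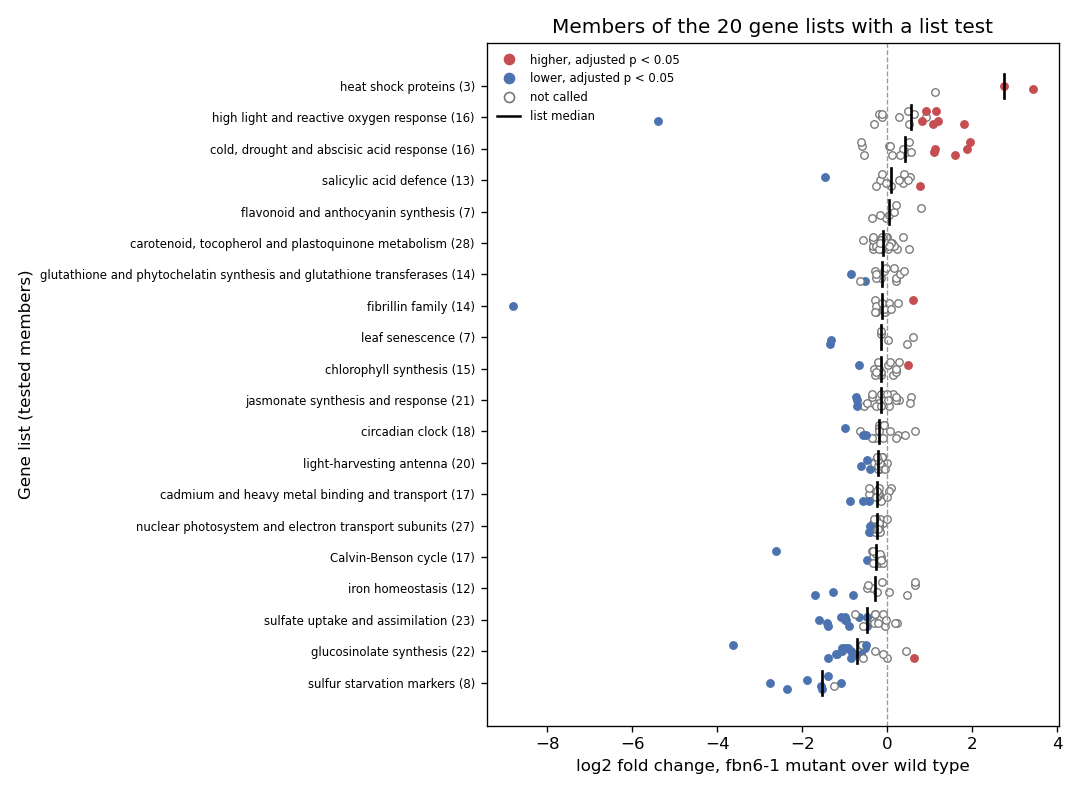
Log2 fold change of the fbn6-1 mutant over wild type (x axis) for the tested members of 20 gene lists (y axis, number tested in brackets); filled points were called, open points were not, and bars are list medians. Sulfur starvation markers (median -1.55), glucosinolate synthesis (-0.71) and sulfate assimilation (-0.49) lie lowest and heat shock proteins (2.74, from 3 genes) highest; with library-size scaling all medians move up by about 0.13, and those of the fibrillin, glutathione and carotenoid lists change sign.

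Among genes of cadmium and heavy metal handling, 3 of 17 fell and 0 rose (4 lower adjusted over the list alone). The metal transporter gene NRAMP1 fell from 13.9 ± 2.16 to 7.50 ± 0.375 CPM (-0.88, SE 0.16, adjusted p = 0.00626). The metallothionein genes MT2A (-0.43, SE 0.11, adjusted p = 0.0458) and MT2B (-0.57, SE 0.15, adjusted p = 0.0497) were close to the threshold. MT2A was called, with 1 library left out, only without wild-type replicate 3, and MT2B only without wild-type replicate 4. HMA2 (-0.43), HMA4 (-0.40) and the vacuolar transporter gene ABCC1 (-0.23) were not called. With library-size scaling 1 member of the list was called lower and 0 higher, and the list median was -0.11. The list was called lower by camera (median -0.24, adjusted p = 0.000197; adjusted p = 0.142 with an estimated correlation). Of 14 genes for glutathione, phytochelatins and glutathione transferases, GSTU20 (-0.85, SE 0.15, adjusted p = 0.00491) and GSTF9 (-0.53, SE 0.12, adjusted p = 0.0217) fell and 0 rose; adjusted over the list alone, 3 were lower and 1 higher. GSTF9 was not called without wild-type replicate 2 or mutant replicates 1 or 3 (adjusted p up to 0.0882). With library-size scaling 1 member of this list was called lower, GSTU20, and 1 higher. GSH1 (-0.27), GSH2 (-0.26) and the phytochelatin synthase gene PCS1 (0.38) were not called, and neither was the list (camera adjusted p = 0.240).

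Of 12 tested genes of the iron list, 3 fell and 0 rose (4 lower and 1 higher adjusted over the list alone). FER1, a plastid ferritin gene, fell from 141 ± 38.8 to 43.2 ± 4.82 CPM (-1.71, SE 0.16, adjusted p = 4.16e-05), and FER4 from 18.5 ± 2.98 to 10.4 ± 2.15 CPM (-0.82, SE 0.17, adjusted p = 0.0147). NAS3, a nicotianamine synthase gene, fell by 1.29 (SE 0.20, adjusted p = 0.0027). The ferritin gene FER3 (-0.46, adjusted p = 0.173) was not called. Of the 12 genes 8 lay below 0 and 4 above, among the latter NAS4 (0.66, adjusted p = 0.0952), IMA3 (0.64) and FRO2 (0.47). NAS4 was the 1 higher gene adjusted over the list alone. Camera called the list lower (adjusted p = 0.0151; adjusted p = 0.305 with an estimated correlation; adjusted p = 0.0744 without mutant replicate 1). FER1 overlaps another gene on the opposite strand by 1334 bp, and FER4 was not called without wild-type replicate 2 or mutant replicates 1 or 3.

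Of the nuclear photosynthesis genes tested, RBCS2B fell most and most others were not called. The called genes were 2 of 17, 3 of 20 and 3 of 27 in the 3 lists below, against 3.82% of all tested genes. RBCS2B (AT5G38420), a gene for the small subunit of Rubisco, fell from 2037 ± 102 to 331 ± 11.4 CPM (-2.62, SE 0.10, adjusted p = 1.81e-09). Its sister copies RBCS1A (-0.24), RBCS1B (-0.34) and RBCS3B (-0.18) were not called; reads of these near-identical copies may have been split by the counting. The CP12-2 gene fell by 0.48 (SE 0.10, adjusted p = 0.0169), which made 2 of 17 Calvin-Benson genes. Of 20 antenna genes, LHCB2.3 (-0.49), LHCB4.3 (-0.63) and LHCB1.4 (-0.40) fell, and of 27 photosystem and electron transport genes FNR1, PSAD2 and PSBQ1 fell (-0.42, -0.42 and -0.40). Adjusted over each list alone, 11 Calvin-Benson, 4 antenna and 16 photosystem genes were lower and 0 higher; DESeq2 called 5, 3 and 6 lower over all tested genes. With TMM all members of the 3 lists lay below 0, with medians of -0.26, -0.21 and -0.25, but with library-size scaling 16, 15 and 25 members did, the medians were -0.13, -0.08 and -0.12, and 1 Calvin-Benson gene and 0 of the others were called. Camera called the 3 lists lower (adjusted p = 1.96e-12, 4.12e-08 and 3.25e-14; adjusted p = 0.142, 0.270 and 0.142 with an estimated correlation). The called antenna and photosystem genes and CP12-2 each lost their call without at least 1 library: leaving out mutant replicate 1 ended all 7 of these calls, with adjusted p up to 0.231, and LHCB1.4 lost its call whichever library was left out.

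In chlorophyll synthesis, HEMA1, the gene for glutamyl-tRNA reductase at the start of tetrapyrrole synthesis, fell from 525 ± 34.9 to 333 ± 7.43 CPM (-0.66, SE 0.09, adjusted p = 0.00138). CHLI2, a magnesium chelatase subunit gene, rose by 0.50 (SE 0.11, adjusted p = 0.0273), and the other 13 of 15 tested genes were not called; adjusted over the list alone, 2 were lower and 1 higher, as DESeq2 also called over all tested genes. CHLI2 was not called without wild-type replicates 2 or 4 or mutant replicates 1 or 2, and the list was not called (camera adjusted p = 0.251). Of 28 genes for carotenoids, tocopherol and plastoquinone, 0 were called, also when adjusted over the list alone; 7 had an unadjusted p under 0.05 and DESeq2 called 1. The list was not called (median -0.10, camera adjusted p = 0.0886), but was without wild-type replicate 3 (adjusted p = 0.0342).

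Of 3 tested heat shock genes 2 rose, and their levels were uneven between mutant libraries. HSP70 (AT3G12580) rose from 6.24 ± 2.09 to 67.9 ± 34.5 CPM (3.42, SE 0.34, adjusted p = 5.38e-05), with 103, 67.1 and 33.9 CPM in mutant replicates 1, 2 and 3. HSP90.1 rose from 2.37 ± 0.233 to 15.7 ± 7.34 CPM (2.74, SE 0.32, adjusted p = 0.000243). The list held 11 genes, of which 3 had enough counts; HSP101 (1.12) was not called over all tested genes with TMM, but was with library-size scaling; adjusted over the list alone, 3 were higher. Of 16 genes of the cold, drought and abscisic acid response, 5 rose, 0 fell and 11 were not called, 3 of which lay below 0 (6 higher adjusted over the list alone); DESeq2 called 2 higher. COR15A rose by 1.59 (SE 0.23, adjusted p = 0.00132), COR15B by 1.95 (SE 0.41, adjusted p = 0.0166), ERD10 by 1.12 (SE 0.25, adjusted p = 0.0220), RD29A by 1.88 (SE 0.46, adjusted p = 0.0387) and COR47 by 1.09. RD29A stood at 9.68, 11.6 and 39.9 CPM in mutant replicates 1, 2 and 3, against 5.57 ± 2.44 CPM in wild type. The CBF genes that act upstream of these genes in cold were not called (CBF1 0.52, CBF2 0.37, CBF3 -0.59). Their group means lay between 1.04 and 4.35 CPM, with SE of 0.46, 0.48 and 0.49, so a 2-fold change could have been missed. Camera called both lists higher (adjusted p = 1.63e-05 for heat shock and 0.000759 for cold; adjusted p = 0.142 and 0.205 with an estimated correlation). Only 1 cold-list gene was called without wild-type replicate 2, wild-type replicate 4 or mutant replicate 3; without the last, the log2 fold change of RD29A was 0.96.

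Most tested genes of the hormone and pigment lists were not called. The called genes were 3 of 21 for jasmonate, 1 higher and 1 lower of 13 for salicylic acid, and 0 of 7 for flavonoids. Over all tested genes 3.82% were called. In the jasmonate list the repressor genes JAZ6 (-0.75, SE 0.11, adjusted p = 0.00138), JAZ9 (-0.72, SE 0.12, adjusted p = 0.0035) and JAZ2 (-0.70, SE 0.15, adjusted p = 0.0207) fell, 3 of 21 genes, and the same number was lower adjusted over the list alone. The synthesis genes LOX2 (0.01) and AOS (-0.15) and the response gene VSP2 (-0.37) were not called. Camera called the list lower (adjusted p = 0.0151; adjusted p = 0.305 with an estimated correlation), but not without wild-type replicate 3 (adjusted p = 0.248) or mutant replicate 1 (adjusted p = 0.104), and JAZ2 was not called without wild-type replicate 2 or mutant replicates 1 or 2. In salicylic acid defence, EDS1 rose (0.76, SE 0.15, adjusted p = 0.0103) and PR2 fell (-1.47, SE 0.38, adjusted p = 0.0460) among 13 genes, with 1 higher and 1 lower adjusted over the list alone. The list was not called (camera adjusted p = 0.115), but was called higher without wild-type replicate 3 (adjusted p = 0.0109) or mutant replicate 3 (adjusted p = 0.0484). EDS1 was not called without wild-type replicate 2 or mutant replicates 1 or 3, and PR2 was called only without wild-type replicate 2. Of 18 flavonoid and anthocyanin genes only 7 had enough counts to be tested, and of these 0 were called by edgeR, over all genes or over the list alone, or by DESeq2; 1 had an unadjusted p under 0.05. Among the 11 not tested, LDOX had 1 count in wild type and 25 in the mutant over 3 libraries each, GSTF12 7 and 23, and MYB111 21 and 3. That list had a median of 0.03 and a camera direction of lower (adjusted p = 0.985).

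Lists read as signs of harvest time, age and organ make-up gave the following. RVE1 (-0.99, SE 0.15, adjusted p = 0.00172), LNK4 (-0.57, SE 0.10, adjusted p = 0.00716) and LNK3 (-0.50, SE 0.11, adjusted p = 0.0170) fell among 18 clock genes, and adjusted over the list alone 5 were lower and 1 higher. The central clock genes CCA1 (-0.20), LHY (-0.30), TOC1 (0.20) and GI (0.25) were not called over all tested genes. LHY was among the 5 that were lower adjusted over the list alone. Camera called the clock list lower (adjusted p = 0.00944; adjusted p = 0.142 with an estimated correlation; adjusted p = 0.0650 without mutant replicate 2). LNK3 was not called without wild-type replicate 4 or mutant replicates 1 or 2, nor LNK4 without mutant replicate 2. With library-size scaling 2 clock genes were called lower and 1 higher, and the list median was -0.07, against -0.20 with TMM. In the senescence list the transcription factor gene NAP (-1.35, SE 0.25, adjusted p = 0.00853) and SEN1 (-1.33, SE 0.34, adjusted p = 0.0454) fell among 7 tested genes, as they did adjusted over the list alone; the list was not called (camera adjusted p = 0.406). NAP was not called without mutant replicates 1 or 2, and SEN1 was called only without wild-type replicate 3. Root markers were too low to test (0 of 9); over 3 libraries each, PYK10 had 3 counts in wild type and 29 in the mutant, and the 8 others had at most 3 in either. Of 12 flower and flowering markers only SOC1 was tested and was not called (-0.24).

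Several of the most changed genes lie outside these lists. CYP78A8 rose from 1.69 ± 0.479 to 14.4 ± 0.988 CPM (3.11, SE 0.21, adjusted p = 1.44e-06), and 5PTASE11 from 1.24 ± 0.941 to 10.5 ± 2.01 CPM (2.98, SE 0.34, adjusted p = 0.000205). PGL5, a 6-phosphogluconolactonase gene, rose from 4.92 ± 0.187 to 20.1 ± 1.00 CPM (2.03, SE 0.14, adjusted p = 2.06e-06). AT1G14250, a nucleoside phosphatase gene, rose by 2.19, AtCDC48B, an AAA-type ATPase gene, by 1.94 and AT3G55646 by 1.78. AT1G06830 fell from 11.9 ± 2.96 to 1.22 ± 0.273 CPM (-3.31, SE 0.26, adjusted p = 6.01e-06). AAP4, an amino acid permease gene, fell from 24.5 ± 5.96 to 5.50 ± 0.532 CPM (-2.14, SE 0.18, adjusted p = 1.28e-05), and AT1G67865, of unknown function, from 110 ± 9.45 to 26.6 ± 1.95 CPM (-2.05, SE 0.11, adjusted p = 9.95e-08). AT3G55240 fell from 9.87 ± 2.02 to 2.32 ± 0.265 CPM (adjusted p = 7.60e-05).

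The plastid share of the counts differed between the genotypes by less than the spread between replicates. Plastid genes held 60.7 ± 1.37% of the counts in wild type and 60.5 ± 1.46% in the mutant (SD, n = 3 each, exact permutation p = 0.7). The counting interval of a library was far narrower than this spread, for example 59.4% (95% interval 59.3 to 59.4) in mutant replicate 1. Mitochondrial genes held 0.294 ± 0.0466% and 0.331 ± 0.0305% (n = 3 each, exact permutation p = 0.5), a difference of 0.0378 percentage points, below the wild-type SD and above the mutant SD. The smallest p this test can give with 3 against 3 libraries is 0.1, so it could not have passed 0.05. The share of both organelles together differed by -0.232 percentage points, mutant minus wild type.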

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

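FBN6 kept its call and direction under every alternative run, with log2 fold changes between -9.12 and -8.68. Of the 61 named genes, 35 kept their call under all 14 alternatives, 26 lost it under at least 1, and 0 changed sign. Against 245 higher and 388 lower genes, library-size scaling gave 508 and 195, of which 440 of the 703 called genes were among the 633; that setting moves all genes by 0.13. No low-count filter gave 505 and 727, and all 633 genes were among them; the cause of the larger count was not tested. An adjusted p under 0.01 left 69 and 151, by construction. Leaving out 1 library gave 84 to 463 higher and 171 to 775 lower genes. The highest counts came without wild-type replicate 3, whose pairs with the other wild-type libraries differed most (chi-square per degree of freedom 13.9 and 13.0, against 4.53 for the remaining pair); the lower counts came with fewer samples. RLE factors, DESeq2, limma-voom, the 1 CPM filter and the removal of organelle genes kept both counts within 1.5 times. Of the 633 called genes, 187 overlap another annotated gene, and leaving such genes out left 171 higher and 275 lower. That alternative was chosen after seeing the data. It is a recount without a new fit, so it does not show whether overlaps affect the calls.

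Replicate numbers 2 and 3 occur in both genotypes, but the labels do not say that they pair samples, and the deviations of same-numbered libraries correlated at -0.03 and 0.10 across genes. With the replicate block, 73 genes were higher and 118 lower, 176 of these 191 being among the 633. Only 1 residual degree of freedom remained, against 4. Wild-type replicate 4 and mutant replicate 1 each had a block of their own. The genotype difference in that fit therefore rested on replicates 2 and 3 of each genotype.

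With an estimated correlation 0 of the 20 lists were called, against 14 with the preset value. Fry, a test of another question, called 8 of the 20. Among these were sulfur starvation markers (fry adjusted p = 0.0203), glucosinolate synthesis (0.0101) and the Calvin-Benson cycle (0.0101). Heat shock proteins (0.0549) and the light-harvesting antenna (0.0565) were among those not called. The estimate for the clock list (0.00848) lay below the preset 0.01, yet its unadjusted camera p rose from 0.00519 to 0.0475. A higher correlation therefore does not account for every lost call, and the 0 calls cannot be read as an effect of correlation alone. The difference in the organelle share moved between -1.05 and 0.527 points when 1 library was left out, within the spread between replicates. The share among protein-coding genes only was not run, because the annotation used does not pair the organelle identifiers with gene types. Depth limits genes of low expression: 8 of 11 heat shock genes and 9 of 9 root markers had too few counts to test.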

Other observations

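The gene families and tests in this part were chosen after the results were seen, except the count of splits. The families were picked by symbol because members had been seen to change, so their counts describe these families only and no test of them is given. Of 6 tested YSL genes, which encode transporters of metal-nicotianamine complexes, YSL1 (-1.54), YSL2 (-1.90), YSL3 (-1.63) and YSL6 (-0.53) fell and 0 rose (median -1.03). Of 6 AAP amino acid permease genes, AAP1 (-0.82), AAP2 (-1.51) and AAP4 (-2.14) fell. Of 21 UMAMIT transporter genes, UMAMIT12 (-1.62), UMAMIT17 (-1.74), UMAMIT20 (-1.46) and UMAMIT30 (-1.01) fell and UMAMIT13 (0.52) and UMAMIT36 (2.67) rose (median -0.16). Of 13 SAUR genes, SAUR20, SAUR24 and SAUR29 fell (median -0.68), and of 15 XTH cell wall genes 5 fell, XTH24 (-1.68) and XTH7 (-1.14) most, and 2 rose. These medians stayed below 0 with library-size scaling (UMAMIT -0.02).

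Of 149 EMB genes, named for embryo defects of their mutants, 10 rose, 0 fell and the rest were not called, with EMB2729 (1.77) and EMB175 (1.28) changed most. Over all tested genes, 245 of 16584 rose. The EMB gene emb2411 (0.87), which also rose, overlaps CSD1 by 211 bp on the opposite strand, so its value is uncertain. PDE312, PDE327 and pde191 rose among 15 PDE genes, named for pigment defects. PTAC14 (0.63) rose among 14 genes with a PTAC symbol, named for the plastid transcription complex. Members of that complex under other symbols are not in this count. Beside HSP70 and HSP90.1, further chaperone and co-chaperone genes, picked from the higher genes, rose: HSP81-2 (1.52), HSP81-3 (1.17), HSC70-3 (1.44), HSC70-1 (0.58), HOP3 (2.47) and FES1A (1.32).

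The real grouping of the 6 libraries gave 633 called genes and the highest of the other 9 splits gave 2. Only 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05.

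Lower FSD1 with higher CSD1 and CSD2 was accompanied by higher CCS (1.76, SE 0.11), the chaperone gene of copper/zinc superoxide dismutases; CSD1, CSD2 and CCS are known targets of miR398, which accumulates in copper deficiency together with FSD1, but the other tested target, COX5b-1 (-0.02), was not called. Reads shared with overlapping genes are argued against for FSD1, CSD2 and CCS, which overlap no annotated gene and changed by at least 1.76, but not for CSD1. A lower activity of the copper-deficiency programme in the mutant is a candidate explanation that stays open: of 5 other tested genes induced by copper deficiency, CCH (-1.70) and YSL2 (-1.90) fell but had prompted the list, which voids a test that includes them (percentile 0), and the 3 left, COPT2 (-1.43, adjusted p = 0.0956), COPT1 (-0.28) and COPT6 (-0.26), were not called, with their median at percentile 7.18 of 10000 random lists matched on expression. AT5G14550, which spans the MIR398b precursor on the opposite strand, fell by 2.62 (SE 0.29, adjusted p = 0.000147), from 7.12 to 1.14 CPM. The deposited counts held no value for MIR398b, and AT5G14550 also overlaps AT5G14560 by 92 bp. Because the use of strand is not stated, the value of AT5G14550 is no measure of MIR398b. Whether copper supply in the soil differed between the plants cannot be told apart from genotype, since 0 growth batches are named in the labels.

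RBCS2B fell while its 3 sister copies were not called. Reads assigned to the sister copies in the mutant are argued against, because their summed level did not rise by what RBCS2B lost. With TMM scaling that level changed by -112% of the loss (SE 36.1), and all 4 copies together stood at 75.6% of wild type. These percentages were not computed with library size only. Unscaled counts, summed over 3 libraries, also fell: RBCS1A from 217518 to 199139, RBCS1B from 40282 to 34300 and RBCS3B from 115149 to 110369. Reads lost for matching several copies would not raise the sister copies, so they are not covered by this test. A sequence or copy difference at RBCS2B in the background of the line could also lower its counts; 0 of the 20 neighbouring tested genes were called, which argues against a large segment but leaves a variant of this gene alone open. An effect of the genotype itself also stays open and untested.

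The sulfur starvation markers were lower with a median of -1.55. It was not carried by any library, since the median was at most -1.29 whichever was left out, nor by scaling, since it was -1.42 with library size only. Harvest at another time of day cannot be told apart from genotype. Morning clock genes minus evening clock genes gave a median difference of -0.42, a direction a shift in time could produce. Of these 6 genes 0 were called over all tested genes, but LHY was lower when adjusted over the clock list alone. Of the clock genes outside these 6, RVE1 (-0.99), LNK4 (-0.57) and LNK3 (-0.50) were called lower and 0 higher. Genotype, and sulfur supply confounded with it, stay open and untested.

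Linked background around the insertion could add calls near FBN6. Of the 200 nearest tested genes 12 were called (6.00%), against 3.81% of 16134 others (odds ratio 1.61, interval 0.814 to 2.91, Fisher's exact p = 0.133), which leaves this open. FBN6 and 249 tested genes with no position in the annotation used, 156 of them plastid or mitochondrial, were left out.

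Neighbouring genes that do not overlap were called in the same direction in 22 pairs, against a mean of 10.8 in 10000 random placements (permutation p = 0.002, one-sided), as for CYP79F1 with CYP79F2, MAM1 with MAM3, COR15A with COR15B and UMAMIT17 with UMAMIT20. Local co-regulation or linked variants may account for such pairs; reads shared between tandem copies were not separated from these.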
